A study of Danio rerio with 3 samples.

How the data were processed

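Gene expression was measured in whole zebrafish embryos on 2-colour Agilent arrays. Per the labels' protocols, 10 to 15 embryos made up each biological replicate, and treated embryos were kept in 40 µM LY-364947 from 8 to 48 hours post fertilisation. RNA of 3 treated replicates was hybridised on 3 arrays, each against the same pool of 3 untreated replicates. Treated RNA carried Cy3 on the arrays of replicates 1 and 3 and Cy5 on the array of replicate 2. Per the labels' protocols, RNA was linearly amplified with T7 polymerase, 3 µg was labelled with a platinum-linked dye, and 2 µg of each sample was hybridised.

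The deposited table holds 1 log ratio per probe and array, read here as log2 values processed by the authors. The submitters' processing notes name Partek without a version. Background correction, normalisation, log base and numerator are not given in the sources used here. The array medians as deposited were -0.0035 for replicate 1, -0.0029 for replicate 2 and -0.0050 for replicate 3, so the ratios were close to centred. Base 2 was taken as likely. The largest single value, 3.98 in size, is 15.8-fold on base 2 and 9524-fold on base 10, and on base 10 the means of 24 probes would exceed 100-fold. The median size of a value is 1.08-fold on base 2 and 1.27-fold on base 10. The SD of control probes is 6.1% on base 2 and 21.7% on base 10. Neither of these excludes base 10. The table holds no intensities, so signal over background is unknown and dim probes could not be left out. No value was missing. The number of arrays limits the precision.

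Over all probes, the deposited ratios of replicate 2 correlated with those of replicate 1 at r = -0.742 and with those of replicate 3 at r = -0.647, and replicates 1 and 3 correlated at r = 0.521. By a rule set before the data were examined, the sign of replicate 2 was therefore turned, and all values run in the sign of replicates 1 and 3. This takes the swapped array as deposited unturned. The sample titles name the treated embryos first on arrays 1 and 3, under which positive values are higher with LY-364947. Cy5 over Cy3, the usual order for Agilent ratios, gives the opposite reading. The direction is not settled by the labels, and none is claimed.

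Of 43648 probes, 45 controls were left out and 43603 were tested. The platform's annotation gave 1 gene symbol for 23717 probes, several for 0 and none for 19886. Probes of a gene were averaged on the log2 scale, giving 15571 genes, 6095 of them with more than 1 probe. Symbols were looked up by Entrez gene identifier in a table of the GRCz12tu assembly, where 15416 genes were found and 0 symbols differed. Probes that share a sequence with close paralogs cannot be told from their gene, which applies most to the crystallin, keratin and haemoglobin families.

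The mean ratio was tested against 0 with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The untreated pool counts as 1 control sample present in every ratio, so the test leaves out the spread between untreated embryos, and any peculiarity of the pool is shared by all 3 arrays. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 36 lists written before the data were examined, with camera at an estimated correlation and fry beside it. Camera at an estimated correlation takes its degrees of freedom from the arrays (2), and at the preset one from the number of genes. A dye term was fitted with 1 residual degree of freedom.

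The genes named were set by a rule written before the data were examined. It took the 12 largest mean ratios on each side among genes past the threshold with 1 sign in all 3 arrays, passing over clone symbols (1 on each side). It added 13 genes fixed by name, of which 10 were measured, and up to 4 members with the smallest adjusted p of each list described. On data simulated for this comparison over 15571 genes, with 200 genes changed in each of 20 runs, limma recovered 13.7% of changes of 0.3 log2 units, 55.2% of changes of 0.5, 89.4% of changes of 1 and 97.8% of changes of 2. False calls made up 2.3% of calls. Fewer genes were changed in these runs than the 3013 called in the data, so the recovery rates need not hold for the data. These runs gave the pool no error of its own, so unchanged embryos were also simulated 20 times against a shared pool with an error, a step added after the data were seen. Alternatives covered centring, scaling, quantile normalisation, the dye term, the prior, a minimum change, the threshold, the rule for probes, the sign of the arrays and leaving out each replicate. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.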

Results

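LY-364947 is a small-molecule inhibitor of TGF-β receptor 1, the kinase that passes TGF-β signals to the SMAD transcription factors. The series set RNA of inhibitor-treated zebrafish embryos at 48 hours post fertilisation against RNA of untreated embryos, so that the comparison asks which transcripts differ after exposure from 8 to 48 hours. There were 3 treated replicates, each on its own array against 1 pool of 3 untreated replicates. The array of replicate 2 had its dyes swapped. The values were log ratios per probe, with no intensities, and the number of arrays limits their precision.

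Every ratio is given in the sign of replicates 1 and 3, with that of replicate 2 turned. Read by the sample titles, a positive value is higher in treated embryos; read as Cy5 over Cy3, it is higher in the untreated pool. The sources did not settle this, so genes are described as lying on the positive or the negative side. The log base was not stated either, and base 2 was taken as likely. If the base were 10, every change would be larger than its fold given here, and the limma test would be the same.

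Lists of cell cycle, Notch and neural progenitor genes shifted to the negative side, and lists of lens, retina, neuron and cartilage genes to the positive side, by camera at a preset correlation. Of the 36 lists, 0 passed with an estimated correlation, where these 7 had an adjusted p of 0.275. With an estimated correlation, camera rests on 2 residual degrees of freedom, so a call is harder to reach. The estimated correlation lay above the preset 0.01 for the cell cycle (0.118), glia and neural progenitors (0.0139), lens (0.0853) and retina (0.0576). It lay below 0.01 for Notch (-0.0023), neurons (-0.0140) and cartilage (-0.0152), where the estimated correlation does not account for the lost call. The estimate is taken from differences between the 3 arrays, so correlation between genes through the shared pool is not in it. Genes past an adjusted p of 0.05 by limma on the negative side numbered 36 of 40 measured for the cell cycle (0 passed on the positive side), 13 of 26 for Notch (1 positive) and 15 of 29 for glia and neural progenitors (5 positive). On the positive side, 28 of 47 lens genes passed (0 passed on the negative side), 20 of 44 retina genes (3 negative), 24 of 48 neuronal genes (1 negative) and 17 of 34 cartilage and bone genes (1 negative). Of 23 TGF-β target genes, 6 passed on the positive and 3 on the negative side, and 14 did not pass.

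Of 15571 genes, 3013 (19.4%) passed an adjusted p of 0.05 by limma, 1545 on the positive side and 1468 on the negative side. Most changes were small, with a median size of 0.33 log2 units among the genes that passed. At least 2-fold changes numbered 79 on the positive side and 25 on the negative side. The 3 arrays had 1 sign for 8145 genes (52.3%). Across genes, which are not independent replicates, ratios correlated between replicates 1 and 2 at r = 0.820, between 2 and 3 at 0.738 and between 1 and 3 at 0.644. The count fell to 1041 without replicate 2 and to 1465 with a dye term, and an ordinary one-sample statistic without shared variance gave 0, with 3417 genes at an unadjusted p of 0.05. Of the 1465 genes, 1463 were also called without the dye term. The dye coefficient itself passed limma for 0 genes, with 111 at an unadjusted p of 0.05. That is fewer than an even spread of p values over 15571 genes would give, so 0 calls do not exclude dye effects. Dye coefficients had an SD of 0.065, against 0.234 for treatment. This fit had 1 residual degree of freedom, so the lower count does not show that calls depend on the dye.

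Every ratio holds the same untreated pool, and the test cannot see the pool's own error. In 20 simulations of unchanged embryos, added after the data were seen, a pool as variable as 1 treated replicate gave a mean of 2097 calls (at most 2547), 49.95% of genes with 1 sign in all arrays and a mean correlation of 0.501. A pool with its variance divided by its 3 replicates gave 90.1 calls (at most 182), 37.2% of genes and a correlation of 0.254. At 2-fold or more, the simulations gave at most 6 calls, against 104 observed. The simulated pool error was independent between genes and at most as variable as 1 treated replicate. A pool difference shared by genes of a tissue or stage was not simulated, so the 2-fold calls are not shown to be free of it. The SDs given for genes and lists leave the pool's error out as well. The spread of the untreated embryos was not measured, so the share of the 3013 calls that comes from the pool is unknown. Calls of small changes are the most open to an error of the simulated kind.

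**Figure D1:**
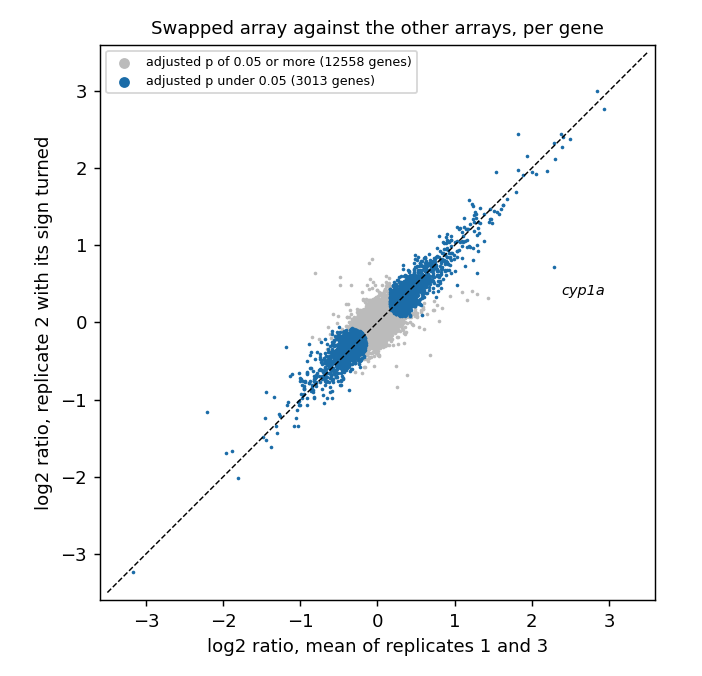
Each point is 1 of 15571 genes, with the mean log2 ratio of replicates 1 and 3 on the horizontal axis and the log2 ratio of replicate 2, its sign turned, on the vertical axis. The 3013 genes that passed adjusted p under 0.05 lie along the dashed line of equal values, and cyp1a, at 0.71 on replicate 2 against 2.39 and 2.18 on replicates 1 and 3, lies below it; whether positive means higher in treated or in untreated embryos is not settled.

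The largest mean ratio on the positive side was that of fgfbp2b, an FGF-binding protein, at 2.90 ± 0.14 (SD, n = 3), a 7.45-fold difference. It was followed by the lens gene crygm2d11 at 2.88 ± 0.22 and by gnb3a, a G-protein β subunit, at 2.46 ± 0.07. The photoreceptor transcription factor crx had a 5.27-fold difference (SD 0.11 log2 units). The retinal transcription factor vsx1 differed 4.93-fold (SD 0.03 log2 units), with the γ-crystallin crygm2d18 at 2.24 ± 0.18 and matn1, a cartilage matrix protein, at 1.98 ± 0.04. The galectin gene lgals1l1 reached 2.35 ± 0.09, the annexin gene anxa1b 2.12 ± 0.32 and the carboxylesterase gene ces3 2.01 ± 0.28. The linker histone gene histh1l1 differed 5.29-fold (SD 0.13 log2 units). The fatty acid binding protein gene fabp4b averaged 2.02 ± 1.34 with 0.53 on replicate 1, 2.44 on replicate 2 and 3.11 on replicate 3, and without replicate 2 its mean of 1.82 did not pass (adjusted p = 0.122, with 1 residual degree of freedom). The 2 probes of ces3 differed, at 1.63 and 2.39. Near-identical γ-crystallin copies can bind each other's probes, so neither crystallin value can be assigned to 1 gene.

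The negative side was led by ctss2.1, a cathepsin, at -3.19 ± 0.21, a 9.13-fold difference. The pancreatic elastase gene cela1.6 stood at -1.88 ± 0.12, acta2, the smooth muscle actin, at -1.87 ± 0.18 and igfbp1a, an insulin-like growth factor binding protein, at -1.81 ± 0.22. Neural progenitor and Notch pathway genes followed: her2 at -1.48 ± 0.04, the glial glutamate transporter slc1a3a at -1.47 ± 0.11, her15.2 at -1.32 ± 0.27 and the progenitor transcription factor sox3 at -1.24 ± 0.07. The others were prtga (-1.46 ± 0.25), phgdh (-1.38 ± 0.13), the linker histone h1-10 (-1.35 ± 0.46) and igf2bp1 (-1.26 ± 0.54). The 2 probes of prtga differed, at -2.25 and -0.68, and the latter alone would not place it among these genes. Adjusted p values by limma of these 24 genes were at most 0.0178, the value of fabp4b.

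**Figure D2:**
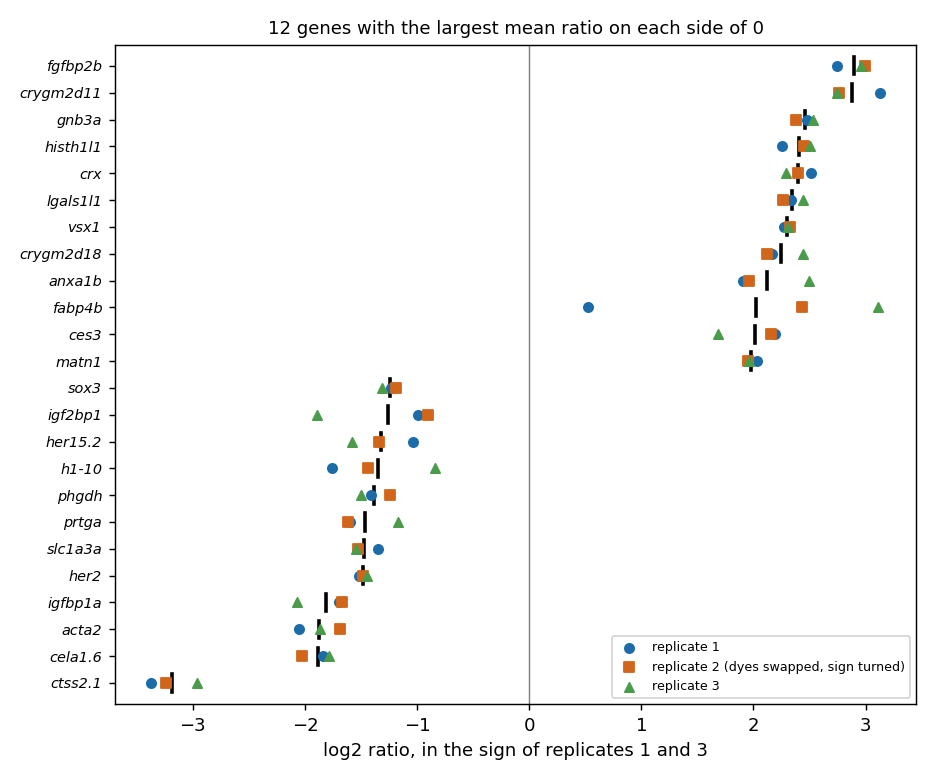
Log2 ratios of the 12 genes with the largest mean ratio on each side, with 1 point per array and a vertical bar at the mean of the 3 arrays. Every gene has 1 sign in all arrays, from ctss2.1 at -3.19 to fgfbp2b at 2.90, and fabp4b has the widest spread at 0.53 to 3.11; whether positive means higher in treated or in untreated embryos is not settled.

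TGF-β pathway genes that passed lay on both sides, most with small changes. The receptor gene tgfbr1a had a mean ratio of 0.06 ± 0.08 (adjusted p = 0.483), smad2 of -0.08 ± 0.06 (adjusted p = 0.336) and smad3b of -0.01 ± 0.10 (adjusted p = 0.956). On the positive side were the pathway targets smad7 at 0.29 ± 0.07 (adjusted p = 0.0112), tgfbi at 0.26 ± 0.02 (0.0122), skilb at 0.31 ± 0.13 (0.0166) and ccn2a at 0.47 ± 0.15 (0.00455). The target pmepa1 had 0.12 ± 0.11 and did not pass (adjusted p = 0.248). On the negative side was smad3a at -0.36 ± 0.17 (0.0152). Of the 2 tgfbi probes, 1 passed (0.45, adjusted p = 0.0102) and 1 did not (0.07, adjusted p = 0.572), so its call rests on 1 probe. Of the smad3a probes, 1 did not pass on its own (-0.17, adjusted p = 0.238). Without replicate 2, the calls of smad7, tgfbi, skilb and ccn2a were lost, although their mean ratios stayed close at 0.289, 0.274, 0.302 and 0.432. With a dye term, the calls of smad3a (adjusted p = 0.0508), smad7 (0.0603), tgfbi (0.0721) and skilb (0.0721) were lost at mean ratios of -0.316, 0.295, 0.256 and 0.312. Both fits had 1 residual degree of freedom, so these losses do not show that the changes depend on the dye or on replicate 2.

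Of 23 measured TGF-β target genes, 6 passed on the positive side and 3 on the negative side, or 6 and 6 adjusted over the list alone. The mean of the list was -0.06 and its median 0.05, and camera, which set its direction at positive, gave an adjusted p of 0.741. The negative members included the contractile genes acta2 and tagln (-0.88 ± 0.13), and the positive ones col1a1a (0.64 ± 0.21) and ccn2a. Of 25 measured components of TGF-β and activin signalling, 2 passed on the positive and 3 on the negative side, with the same counts adjusted over the list alone. The activin receptor gene acvr1ba stood at 0.72 ± 0.43 (limma adjusted p = 0.0151), with 0.41, 0.54 and 1.22 on replicates 1, 2 and 3. Besides smad3a, fstl1a (-0.22 ± 0.04, adjusted p = 0.0271) and gdf11 (-0.20 ± 0.05, adjusted p = 0.0387) passed on the negative side.

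Cell division genes moved together. Of 40 measured members, 36 passed on the negative side and 0 on the positive side (38 and 0 adjusted over the list alone), with a list mean of -0.40 ± 0.07 (SD, n = 3 arrays). Examples were pcna, the replication clamp, at -0.80 ± 0.05, the replicative helicase subunit mcm2 at -0.70 ± 0.04, stmn1a at -0.62 ± 0.02 and gins2 at -0.60 ± 0.06. Camera gave an adjusted p of 6.66e-19 at the preset correlation, and adjusted p = 0.275 with an estimated correlation.

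The lists of Notch pathway and neural progenitor genes shifted to the same side. Of 26 measured Notch genes, 13 passed on the negative side and 1 on the positive side (14 and 1 adjusted over the list alone), with a list mean of -0.31 ± 0.02 and a camera adjusted p of 0.000247. Besides her2 and her15.2, dla, a Delta ligand, stood at -1.04 ± 0.21 and lfng, which modifies Notch, at -0.67 ± 0.15. Of 29 glial and neural progenitor genes, 15 passed on the negative and 5 on the positive side (16 and 7 adjusted over the list alone), with a list mean of -0.22 ± 0.03 and an adjusted p of 0.00251. The progenitor transcription factors sox19a (-0.94 ± 0.06) and ascl1a (-0.97 ± 0.11) were among them. With an estimated correlation, both lists had an adjusted p of 0.275.

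The lists of differentiated eye genes shifted to the positive side. In the lens list, 28 of 47 measured genes passed on the positive side and 0 on the negative side (30 and 0 adjusted over the list alone), with a mean of 0.54 ± 0.05 and a camera adjusted p of 3.77e-15. Examples were the crystallins crygm2d11, crygmx (1.60 ± 0.15), crygm2b (1.42 ± 0.11) and crygm2d13 (2.63-fold, SD 0.13 log2 units), which share sequence. Of 44 retina and photoreceptor genes, 20 passed on the positive and 3 on the negative side (22 and 3 adjusted over the list alone), with a mean of 0.46 ± 0.03 and an adjusted p of 2.23e-09. Besides crx and vsx1, rpe65a, an enzyme of the visual cycle, stood at 1.76 ± 0.10 and the transcription factor otx5 at 1.49 ± 0.04, although its 2 probes differed, at 0.82 and 2.16. The 3 negative members were rx1 (-0.59), atoh7 (-0.59) and unc119b (-0.29), of which the first and second are transcription factors of early retinal cells; they were chosen after their values were seen. With an estimated correlation, both lists had an adjusted p of 0.275.

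The neuronal list shifted to the positive side as well. Of 48 measured, 24 passed on the positive and 1 on the negative side (27 and 2 adjusted over the list alone), with a mean of 0.29 ± 0.01 and a camera adjusted p of 3.27e-10, or adjusted p = 0.275 with an estimated correlation. The synaptic genes sypb (0.87 ± 0.01) and snap25b (0.75 ± 0.07), the G-protein subunit gene gng3 (0.70 ± 0.03) and the transcription factor gene isl1a (0.70 ± 0.08) had the smallest adjusted p.

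Lists of skeletal and connective tissue shifted to the same side. Of 34 cartilage and bone genes, 17 passed on the positive and 1 on the negative side (18 and 1 adjusted over the list alone), with a mean of 0.30 ± 0.01 and a camera adjusted p of 5.62e-08. Next to matn1 stood the collagen genes col10a1a (1.67 ± 0.29), col9a2 (0.78 ± 0.12) and col9a3 (0.65 ± 0.12), of whose probes 1 did not pass on its own (0.26, adjusted p = 0.136). Of 32 collagen and matrix genes, 16 passed on the positive and 0 on the negative side (17 and 1 adjusted over the list alone), with a mean of 0.22 ± 0.04 and an adjusted p of 3.44e-06. Examples were the proteoglycan genes vcanb (1.12 ± 0.29) and lum (0.56 ± 0.11), and matn3a (0.54 ± 0.06), of whose probes the lowest had 0.02. Of 19 genes for matrix crosslinking and latent TGF-β, 8 passed on the positive and 1 on the negative side (10 and 1 adjusted over the list alone), with a mean of 0.12 ± 0.02 and an adjusted p of 0.00824. The elastic fibre genes fbln5 (0.40 ± 0.09) and efemp2b (0.38 ± 0.10) had the smallest adjusted p. Without replicate 2, efemp2b stayed at 0.354 and did not pass (adjusted p = 0.0705, with 1 residual degree of freedom), and 1 of the fbln5 probes did not pass on its own (0.22, adjusted p = 0.137). With an estimated correlation, the adjusted p of these 3 lists was 0.275.

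Skin genes split within the list. Of 54 epidermis and fin fold genes, 19 passed on the positive and 6 on the negative side (21 and 6 adjusted over the list alone), with a mean of 0.23 ± 0.06 and a camera adjusted p of 0.00138, or adjusted p = 0.453 with an estimated correlation. The actinodin genes and3 (1.65 ± 0.16) and and2 (1.43 ± 0.08), which form the fibres of the fin fold, and the keratin gene krt1-19d (1.46 ± 0.07, with probes at 1.07 and 1.86) lay on the positive side with lgals1l1.

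The muscle and vascular lists shifted to the positive side by camera at the preset correlation, although most of their members did not pass. Of 54 skeletal muscle genes, 12 passed on the positive and 2 on the negative side (15 and 4 adjusted over the list alone), with a mean of 0.13 ± 0.01 and a camera adjusted p of 0.00362. The mitochondrial creatine kinase gene ckmt2a stood at 1.32 ± 0.28, the actin gene acta1b at 0.91 ± 0.25 and the myosin light chain gene mylpfb at 0.63 ± 0.10. In contrast, desma, encoding desmin, stood at -0.53 ± 0.05. Of 38 vascular genes, 7 passed on the positive and 0 on the negative side, with the same counts adjusted over the list alone, a mean of 0.09 ± 0.03 and an adjusted p of 0.0107. The tight junction gene cldn5b (0.49 ± 0.03) and the water channel gene aqp1a.1 (0.38 ± 0.05) led it. The vascular call was lost without replicate 1 (camera adjusted p = 0.0595), at a mean of 0.076. By fry, which tests a list against no change and not against other genes, the adjusted p was 0.0129 for muscle and 0.0735 for vessels. With an estimated correlation, the adjusted p was 0.275 for muscle and 0.509 for vessels.

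The erythroid, innate immune and p53 lists shifted to the negative side by camera at the preset correlation, although most of their members did not pass. Of 28 erythroid genes, 6 passed there and 0 on the positive side (7 and 0 adjusted over the list alone), with a mean of -0.18 ± 0.06 and a camera adjusted p of 0.00138. The embryonic globin genes hbbe3 (-1.12 ± 0.29) and hbbe2 (-0.63 ± 0.21), open to cross-hybridisation, were among them. Of 24 innate immune genes, 7 passed there and 0 on the positive side, with the same counts adjusted over the list alone, a mean of -0.17 ± 0.04 and an adjusted p of 0.00824. The cytokine signalling inhibitors socs3a (-0.87 ± 0.27) and socs3b (-0.70 ± 0.08) and the protease gene mmp9 (-0.76 ± 0.31) were examples. Of 18 p53 target genes, 5 passed there and 0 on the positive side (7 and 1 adjusted over the list alone), with a mean of -0.20 ± 0.07 and an adjusted p of 0.0151. Its leading members sesn2 (-0.85 ± 0.18) and btg2 (-0.85 ± 0.19) also answer to other stresses. With an estimated correlation, the adjusted p was 0.509 for the erythroid, 0.275 for the immune and 0.390 for the p53 list. Against no change, fry gave 0.0984, 0.0613 and 0.0664 in the same order. The list of myeloid cells did not pass camera (adjusted p = 0.402) but passed fry (adjusted p = 0.0160), with a mean of -0.08 ± 0.01.

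The other 21 of 36 lists did not pass camera. In the aryl hydrocarbon receptor list, 3 of 16 genes passed on the positive and 4 on the negative side, with the same counts adjusted over the list alone and a camera adjusted p of 0.992. Its marker cyp1a averaged 1.76 ± 0.92 (limma adjusted p = 0.00748), with 2.39 on replicate 1, 0.71 on replicate 2 and 2.18 on replicate 3. The heat shock and unfolded protein response list had 3 of 30 genes past the threshold on the positive and 7 on the negative side (4 and 8 adjusted over the list alone), with a mean of -0.12 ± 0.18 and an adjusted p of 0.146, and its array means ran from -0.32 on replicate 1 to 0.03 on replicate 3. Its mean was -0.016 without replicate 1 (adjusted p = 0.833), -0.148 without replicate 2 (0.0399) and -0.191 without replicate 3 (0.00873). Liver and yolk genes had a mean of 0.06 ± 0.09 over 42 genes and an adjusted p of 0.832. Pancreas genes had a mean of 0.11 ± 0.07 over 29 genes and an adjusted p of 0.153. Without replicate 3, the adjusted p of the pancreas list became 0.0161 at a mean of 0.154. Of the pancreas genes, 5 passed on the positive side, among them prss1 (1.32) and neurod1 (1.02). Another 2 passed on the negative side, among them sst2 (-0.485). Mean, median and the direction of the test differed in sign for the lists of TGF-β targets, TGF-β components, BMP, aryl hydrocarbon receptor and retinoic acid response, circadian clock, heart and smooth muscle.

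**Figure D3:**
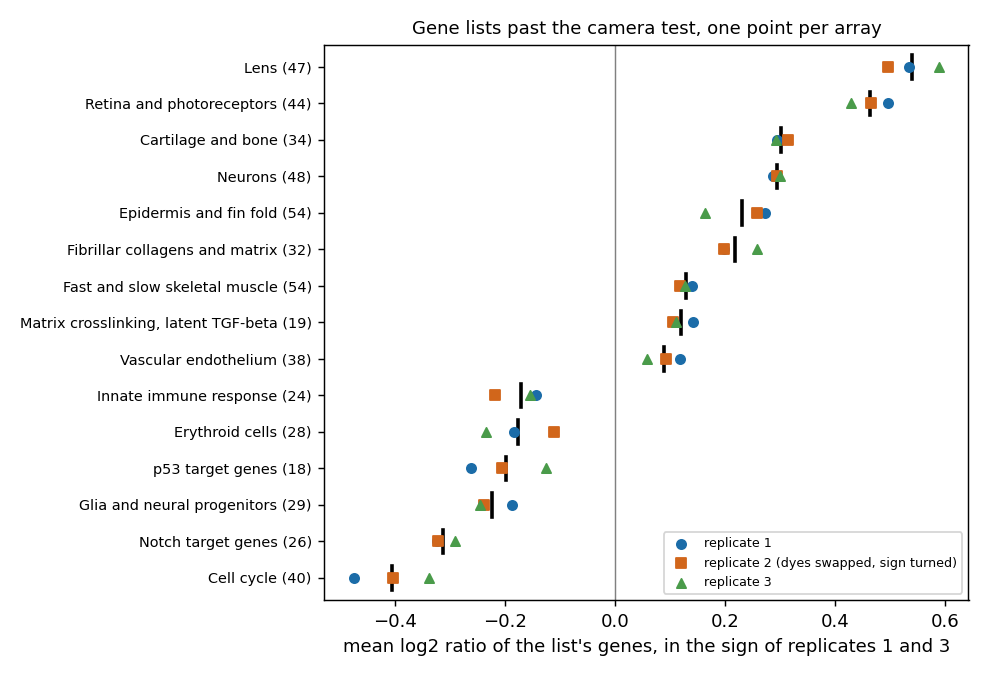
Mean log2 ratio of the measured genes of each of the 15 lists past camera at the preset correlation, with the number of genes in brackets, 1 point per array and a vertical bar at the mean of the 3 arrays. All 3 arrays of each list share a sign, from -0.40 for the cell cycle to 0.54 for the lens, 0 of 36 lists pass with an estimated correlation (5 at an unadjusted p of 0.05), and whether positive means higher in treated or in untreated embryos is not settled.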

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

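Of 15571 genes, 3013 were called in the values as turned, and between 2731 and 4138 under centring, scaling, quantile normalisation, a robust prior, other rules for probes or an adjusted p of 0.1. Turning every sign gave 3013 calls with 1468 positive and 1545 negative. The count was 1465 with a dye term (1210 against 4522 for probes), 505 against a minimum change of 1.2-fold (315 positive, 190 negative) and 104 at 2-fold or more. That last count would be 1761 on base 10, an alternative chosen after the data were seen. It was 0 with an ordinary one-sample statistic (3417 at an unadjusted p of 0.05) and 0 with the swapped array's sign as deposited (34). Leaving out 1 replicate gave 1041 to 3693 genes and 621 to 6539 probes, in each case lowest without replicate 2. Of those 1041 genes, 1033 were also called with all arrays. The lowest count came from the pair with the lowest correlation across genes, replicates 1 and 3 (r = 0.644). The highest came from the pair with the highest correlation, replicates 1 and 2 (r = 0.820). Beyond this, the cause was not tested. Lists past camera numbered 15, with the same 15 under a dye term. They numbered 0 with an estimated correlation (5 at an unadjusted p of 0.05) and 14 to 17 with 1 replicate left out. By fry, which asks whether a list moves from no change and not whether it differs from other genes, 14 lists passed. They included 11 of the 15 but not p53, innate immune, vascular and erythroid, and the others were Hedgehog, FGF and myeloid.

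Some uncalled values changed sign, and the cause was not tested. With 1 replicate left out, list means ranged from -0.0019 to 0.065 (BMP), -0.0026 to 0.086 (aryl hydrocarbon receptor), -0.044 to 0.0075 (retinoic acid), -0.0063 to 0.054 (circadian), -0.013 to 0.031 (heart) and -0.032 to 0.0037 (pigment), and smad3b from -0.050 to 0.048. A dye term put smad3b at 0.015, and single probes had 0.080 for smad3b, 0.053 for smad2 and -0.011 for tgfbr1a. Of 85 named genes, 10 lost their call with a dye term, 4 without replicate 1, 13 without replicate 2 and 1 without replicate 3. Missing values and dim probes could not be varied, because the table marks none. No paired analysis was possible because the only control was 1 pool.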

Other observations

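The 6 gene lists in this part, the comparison of probe pairs, the readings of the cartilage and liver lists, the spread of the cyp1a probes, the use of the dye coefficient for cyp1a and the sign test were chosen after the values had been seen; the probe-level test and the fit with a dye term were planned. The 6 lists are therefore no independent evidence. Of them, 5 lists of protein synthesis, amino acid supply, stress and purine genes shifted to the negative side by camera at the preset correlation, and 0 of the 6 passed with an estimated correlation (adjusted p of 0.0955 to 0.369). Of 17 cytosolic aminoacyl-tRNA synthetase genes, which load tRNAs with amino acids, 12 passed on the negative side and 0 on the positive side, with a mean of -0.39 ± 0.08 (SD, n = 3 arrays), among them nars1 (-0.82) and tars1 (-0.69). Of 38 ribosome biogenesis genes, 19 passed there and 0 on the positive side, with a mean of -0.26 ± 0.02, led by the RNA helicase gene ddx21 (-0.96). Of 21 genes linked to the stress transcription factor ATF4, 17 passed on the negative and 1 on the positive side, with a mean of -0.55 ± 0.13, among them trib3 (-0.93), atf3 (-0.87) and asns (-0.65). These 3 genes, ddit3 (-0.69), chac1 (-0.63), atf4a (-0.52) and atf4b (-0.21, which did not pass) were also members of the planned heat shock and unfolded protein response list. That list did not pass (mean -0.12 ± 0.18, camera adjusted p = 0.146). Of its 30 genes, 3 passed on the positive and 7 on the negative side, most of the latter from this overlap. Serine and one-carbon genes (mean -0.28 ± 0.11, 5 of 11 passed on the negative and 1 on the positive side) included phgdh (-1.38) and psat1 (-1.21) but also mthfd1a on the positive side. Purine synthesis genes (mean -0.22 ± 0.01, 5 of 12 passed on the negative and 2 on the positive side) included paics and gart, both at -0.83.

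The other list, of the fin fold, shifted to the positive side in the same test. Of 12 actinodin and posterior hox genes, 8 passed on the positive side and 0 on the negative side, with a mean of 0.59 ± 0.06, and hoxb13a (0.85) and hoxc13a (0.70) accompanied the actinodins. Adjusted over these 6 lists, camera gave at most 0.0150 at the preset correlation. Among 19886 probes without a gene symbol, 938 passed, and the largest, A_15_P565937, had -3.69 ± 0.10 (SE), larger in size than any named gene among the 24 with the largest ratios.

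Lists of dividing and progenitor cells lay opposite to lists of lens, retina, neurons and cartilage. Dye bias tied to probe sequence, as the whole cause, was argued against by pairs of probes for 1 gene. This holds as far as these differ in sequence, which is not known here. Over all genes, 69.0% of 10806 pairs shared a sign, against at most 51.5% in 1000 shufflings of the probes. Among 269 members of the 15 shifted lists, whose selection by mean favours probes that agree, it was 75.7% of 642 pairs against at most 59.8%. Differences in expression also make such pairs agree, so a part for dye bias is not excluded. If replicate 2 was deposited unturned, as taken here, a dye bias would have the opposite sign on it once turned. Its turned gene ratios correlated with those of replicates 1 and 3 at r = 0.820 and 0.738. Under that reading, these values argue against dye bias as the main source. However, replicate 2 was turned because of its negative correlation with the other arrays, so the positive sign is no separate test. Had replicate 2 been deposited already turned, a dominant dye bias would give the same values, so they do not exclude it. With a dye term, the same 15 lists passed camera at the preset correlation. A different share of eye tissue as the whole cause was argued against by the cartilage and bone list, at 0.30 ± 0.01. That list is itself part of the pattern, so it is no separate test, and its SD leaves out the pool's error. A difference in developmental stage cannot be told apart from a direct effect of the inhibitor, because both would be present in every ratio. The list of liver and yolk genes, at 0.057 ± 0.085, decided nothing. Its members split, with 6 passed on the positive and 5 on the negative side. Those with the smallest adjusted p were fabp10a, uox and hpda, at 0.799 to 1.87, and apoa4a, at -0.603. All but apoa4a lay on the side of the lens, retina, neuron and cartilage lists. These members were picked by adjusted p and do not settle the question of stage. A peculiarity of the single pool also stays open, and the treatment itself was not tested against it. A pool error independent between genes would not move whole lists, but one shared by genes of a tissue or stage would.

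The cyp1a ratio was 0.71 on replicate 2 against 2.39 and 2.18 on the other arrays. A single poor probe was argued against, since the 3 cyp1a probes spanned 0.101 log2 units on replicate 2. Dye bias at cyp1a and a weaker response in that replicate cannot be told apart, because 1 array carries the swapped dyes; the dye coefficient was 0.79, with the smallest unadjusted limma p of all genes (6.43e-05), and did not pass after adjustment (0.518) in a fit with 1 residual degree of freedom.

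The numerator of the ratio stays open. If positive values were higher in untreated embryos, called TGF-β target genes would be mostly positive, and 6 of 9 were, with an exact two-sided sign test p of 0.508. The negative acta2 and tagln and the positive smad7 and ccn2a point to opposite readings, so these genes cannot decide it.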
